A study of Homo sapiens and Homo sapiens
human gammaherpesvirus 4 with 12 samples.

How the data were processed

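Small RNA was measured in 12 libraries: whole cells and exosomes of the gastric cancer lines AGS (negative for Epstein-Barr virus, EBV) and SNU-719 (EBV-positive), with 3 libraries in each of the 4 groups. Per the labels' protocols, RNA was extracted with TRIzol, a gel band of 17 to 32 nt was taken for the libraries, the lines grew in different media (F12 for AGS, RPMI-1640 for SNU-719) with 5% serum freed of exosomes, and no treatment was applied. The submitters' processing notes name FastQC and edgeR; their versions and roles, the aligner, the miRNA reference and the treatment of reads that match several loci are not given in the sources used here. The deposited tables, 1 for human and 1 for EBV mature miRNAs, hold per the file headers 1 column per library in RPM (reads scaled to a library total of 1000000). All 24 columns were used and 0 were left out.

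Both tables were summed per library: the human values add up to 1000000 RPM in every library, and so do the EBV values, so a level in the EBV table is a share of EBV reads. In each library the read total was therefore searched under which the most RPM values become whole reads, and the values were turned back into whole reads with it. Of the human values, 93.37 to 96.81% lay within rounding of a whole number (tolerance 0.0051 RPM), against 1.02 to 12.8% expected by chance, and 98.98 to 100% within 0.2 reads, against 40% by chance; for EBV 100% did. On simulated libraries the totals came back exactly in 12 of 12 cases. The recovered totals ran from 996122 to 12550647 human reads, so 1 read was worth 0.0797 to 1.0039 RPM and changes of rare miRNAs in the shallow exosome libraries are imprecise.

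Human miRNAs with identical values in every library were merged, as they cannot be told apart in the fits. Entries of 1 sequence share their reads, but equal values can also be a coincidence: of 373 merged entries 237 had reads in 1 library only. Counts of detected miRNAs are of merged entries, except those after thinning and those given as without merging. Of 2656 human entries, 1833 were above 0, 1536 were left after merging, and the 760 with at least 1 RPM in at least 3 libraries were tested; these hold at least 99.403% of the RPM of every library. The number of copies in the genome was compared with the values for some miRNAs encoded at several loci. Of those checked, miR-105-5p (12 of 12 libraries) and miR-129-5p (11 of 11), with 2 loci each, and miR-1244 (5 of 5), with 4 loci, had read numbers that were always multiples of the number of loci. Their levels can thus be counted more than once. This was not so for miR-7-5p, miR-26a-5p, miR-16-5p, miR-194-5p, miR-92a-3p, let-7a-5p, let-7f-5p and miR-486-5p. Further miRNAs with several loci, such as miR-9-5p, miR-512-3p and miR-516a-5p, were not checked and can be counted more than once as well.

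Groups were compared with limma 3.58.1 (trend) on log2(RPM + 1), in 1 fit of 4 group means over all 12 libraries, and p-values were adjusted by Benjamini-Hochberg within each comparison; adjusted p under 0.05 is called. The 5 comparisons are exosome against cell in each line, SNU-719 against AGS in cells and in exosomes, and the interaction, which is the exosome-to-cell change in SNU-719 minus that in AGS. All p-values are two-sided. EBV miRNAs with at least 1 RPM in at least 3 libraries were tested the same way over the 6 SNU-719 libraries. Differences in detection, in concentration and in EBV load between groups of 3 were tested by exact permutation, where the smallest possible two-sided p is 0.1. The planned total of EBV RPM is the same in every library by construction, and EBV reads per human read were used in its place. Errors are the standard error (SE) of the log2 change, or the SD over 3 libraries. Because the third libraries stood apart, values for replicates 1 and 2 together and for replicate 3 are given beside part of the pooled ones.

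The miRNAs named are, per comparison, the 12 called ones with the highest and the 12 with the lowest change among those whose groups did not overlap and whose higher mean was at least 10 RPM; the 10 most abundant of each group; the members of the lists; and all EBV miRNAs. Against a group with 0 reads the fold is given as "at least", with 3 reads over that group as a floor (the upper 95% bound for 0); against 1 to 3 reads the ratio of reads is given with its 95% counting interval. Such floors and intervals cover counting error only. Fixed lists were 15 of miRNAs (miR-200 family, let-7 family, miR-17-92 and paralogues, gastrointestinal epithelium, HOX clusters, NF-kB and EBV induced host miRNAs, p53 induced miR-34 family, 14q32 imprinted cluster, C19MC and miR-371 cluster, Xq miR-506 to miR-514 cluster, miR-183 cluster, miR-99, miR-100 and miR-125 family, miR-320 family, mirtrons and G-rich or splicing derived miRNAs, entries overlapping other RNAs), 6 of markers (erythroid and blood cell, liver, muscle, stromal and smooth muscle, endothelial, neural) and 4 of EBV miRNAs (BART cluster 1, BART cluster 2, BART2, BHRF1). The 18 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, which asks whether the members changed more than other miRNAs, with Benjamini-Hochberg adjustment over the lists of a comparison. The liver, endothelial and neural lists had fewer members and got no test. Alternatives were camera with an estimated correlation and fry, whose p tests whether the members move one way on balance without comparing them with other miRNAs.

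Groups, tests, lists, the naming rule and alternatives were fixed before the data were examined: pseudocounts of 0.1 and 10 RPM, no filter, a filter at 10 RPM, median-of-ratios scaling, quantile normalization, only the 2 groups compared, a replicate block, a 2-fold minimum, no trend, each library left out in turn, and for EBV also the share within the virus and a joint fit with human miRNAs. Chosen after the data were seen were edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered whole reads, a term for the third replicates, a fit without the third replicates (8 libraries), EBV reads relative to human reads, detection after thinning every library to 996122 reads, the replicate block in the list test, detection without merging, and the list test without each library. Whole reads gave edgeR calls of 74, 137, 147, 93 and 0 miRNAs in the order of comparisons above. The pairing of libraries comes from the replicate numbers in the labels alone and was checked by correlating the deviations of same-numbered libraries from their group means: the 3 correlations were 0.24, 0.243 and 0.333 between SNU-719 exosomes and cells, 0.332, 0.132 and 0.261 between the cells of both lines, 0.303, 0.31 and 0.48 between their exosomes, and -0.064, 0.049 and -0.011 between AGS exosomes and cells, so the replicate number was not taken as a pair in the last. Elsewhere only number 3 was told from the others: across numbers 1 and 2 the correlations were 0.24 and 0.245 between SNU-719 exosomes and cells, 0.117 and 0.211 between the cells and 0.331 and 0.305 between the exosomes.

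The tests were tried on simulated data with 760 miRNAs, of which 200 were changed, in 20 simulations per comparison. For SNU-719 exosomes against cells limma found 4.22, 21.3, 45.2 and 67.3% of changes of 2, 4, 8 and 16-fold, for AGS exosomes against cells 5.81, 17.1, 38.4 and 63.3%, for cells of both lines 4.81, 19, 42.1 and 62.8%, and for exosomes of both lines 8.03, 20.8, 41.8 and 64.9%. In the same order, 11.1, 18.2, 16.1 and 28.8% of its calls were false where the changed miRNAs shifted the RPM totals, and 4.51, 3.66, 3.45 and 4.41% where the totals were held; with edgeR (5 simulations) these shares were 3.86, 3.2, 2.59 and 2.91%. With nothing changed, limma called 0.3, 0.05, 0.05 and 0.15 miRNAs on average. With libraries shuffled (100 shuffles, SNU-719 exosomes against cells), camera at the preset correlation called on average 1.96 (at most 7) of 17 lists that had not been moved, and 0 with the estimated correlation, which found the moved list in 12 of 100 shuffles. With values shuffled within each miRNA, which removes the correlation between miRNAs, the preset called 0.01 on average. For 43 EBV miRNAs, 15 of them changed (50 simulations), 57.2, 91.6 and 97.2% of changes of 4, 8 and 16-fold were found and 3.61% of calls were false. These miRNAs were also drawn independently.

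Positions come from GENCODE 29 on GRCh38. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Raw reads, target prediction and functional annotation of targets were not analysed here. A camera call at the preset correlation is given with its p at an estimated correlation where that p is not under 0.05.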

Results

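Small RNA was sequenced from cells and from exosomes, small vesicles released into the culture medium, of 2 gastric cancer cell lines. AGS is a gastric adenocarcinoma line without EBV, and SNU-719 is a gastric carcinoma line that carries EBV. Each of the 4 groups had 3 libraries, with values in RPM for human and for EBV mature miRNAs. The human reads of replicates 1, 2 and 3 were 12550647, 5840808 and 11872072 in AGS cells and 8862330, 12304279 and 7682787 in SNU-719 cells. The exosome libraries held 1672616, 2470752 and 9210955 human reads in AGS and 1070145, 996122 and 8207548 in SNU-719. With 1 line of each EBV status, an effect of the virus cannot be told from any other difference between the lines. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples, which can be technical. Changes are given on the log2(RPM + 1) scale, which understates those of low miRNAs, with the SE and with n = 3 per group unless stated.

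The small RNA of AGS cells was dominated by miR-372-3p, a miRNA of embryonic stem cells, which made up 43.5% of human RPM (SD 3.35, n = 3). It made up 27.4% (SD 15.6) in AGS exosomes. Next came miR-21-5p, a miRNA high in many carcinomas, with 12.5% in AGS cells (SD 1.18), 12.1% in AGS exosomes (SD 0.80), 14.1% in SNU-719 cells (SD 1.15) and 15.4% in SNU-719 exosomes (SD 3.34). In SNU-719 cells miR-7-5p (8.07%, SD 3.37), miR-92a-3p (7.56%, SD 2.37), miR-148a-3p (7.24%, SD 0.34), miR-194-5p (6.78%, SD 0.93) and miR-192-5p (5.94%, SD 1.35) followed. In SNU-719 exosomes these places were held by miR-148a-3p (11.04%, SD 2.71), miR-7-5p (8.58%, SD 5.69), miR-192-5p (7.20%, SD 2.14) and miR-194-5p (5.09%, SD 3.65). The 10 most abundant miRNAs together made up 77.6% of RPM in AGS cells (SD 1.53), 69.4% in AGS exosomes (SD 4.08), 65.0% in SNU-719 cells (SD 1.79) and 69.9% in SNU-719 exosomes (SD 2.06). The share was higher in AGS cells than in AGS exosomes and lower in SNU-719 cells than in SNU-719 exosomes in every library (exact two-sided p = 0.1 each, the smallest that 3 against 3 libraries can give, adjusted p = 0.133).

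Line and RNA population separated the libraries first, and the third replicates stood apart. The first 3 principal components held 44.3, 31.3 and 9.93% of the variance. On the third component the third exosome libraries lay at -24.77 (AGS) and -31.5 (SNU-719), against -4.47 to 10.07 for all others. Replicates 1 and 2 of a group correlated at 0.994, 0.976, 0.997 and 0.969 (AGS cells, AGS exosomes, SNU-719 cells, SNU-719 exosomes; Pearson on log2 values, over miRNAs that are not independent replicates). With replicate 3 the correlations were 0.855 to 0.973. The spread exceeded counting noise between replicates 1 and 2 (chi-square per degree of freedom 57.66 in AGS cells, 98.6 in AGS exosomes, 101.9 in SNU-719 cells and 116.7 in SNU-719 exosomes), and more so with replicate 3 (569.6 to 4237).

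In SNU-719 exosomes, several miRNAs known from blood, vessel wall and liver stood far above their level in the cells. Of 10 blood cell markers 8 had positive changes. The blood cell miRNA miR-142-3p stood lower in exosomes (154.18, 76.3 and 67.62 RPM) than in cells (813.44, 570.37 and 210.6 RPM). The red cell miRNA miR-486-5p rose by 7.84 on the log2 scale (SE 1.47, adjusted p = 0.00756), from 6.93 RPM (SD 0.946) to 2291 RPM (SD 1487). The endothelial miR-126-3p, from an intron of EGFL7 on chromosome 9 (136670602 to 136670686, plus strand), rose by 6.92 (SE 1.15, adjusted p = 0.00404). The liver miRNA miR-122-5p, from chromosome 18 (58451074 to 58451158, plus strand), rose by 5.90 (SE 0.72, adjusted p = 0.00053), from 2.19 RPM (SD 3.18) to 137 RPM (SD 14.5). The largest losses were those of miR-7974, from an intron of ZNF653 on chromosome 19 (11495544 to 11495622, minus strand), and miR-4521, from chromosome 17 (8186945 to 8187004, plus strand, outside annotated genes). miR-7974 stood at 187 RPM in the cells (SD 112) and had 0 exosome reads, at least 688-fold less, and miR-4521 fell by 5.53 (SE 0.80, adjusted p = 0.00181).

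Within replicates 1 and 2 and within replicate 3, the rises were 8.63 and 6.24 for miR-486-5p, 8.29 and 4.20 for miR-126-3p, and 6.60 and 4.49 for miR-122-5p, and the change of miR-4521 was -4.67 and -7.24. A pair of entries that overlap other small RNAs also ranked high. miR-1246, on chromosome 2 (176600980 to 176601052, minus strand), rose by 7.02 (SE 1.18; 5.11 and 10.85 in the same order, adjusted p = 0.00404). miR-1290, from an intron of ALDH4A1 on chromosome 1 (18897071 to 18897148, minus strand), rose by 6.47 (SE 1.26; 4.61 and 10.21, adjusted p = 0.00777). The stromal miR-143-3p rose by 5.89 (SE 1.08; 7.98 and 1.70, adjusted p = 0.00635), and miR-369-3p of the imprinted 14q32 cluster by 3.09 (SE 0.52; 2.87 and 3.52, adjusted p = 0.00404). miR-412-5p, of the same region but not in the fixed list, had 0 cell reads, at least 284-fold less than in exosomes. miR-6529-5p (1 cell read, ratio 1438, interval 257 to 56897) and miR-345-3p (3 cell reads, ratio 276, interval 93.6 to 1347) were higher in exosomes too. Also lower in exosomes were miR-582-5p (fell by 3.64, SE 0.55), miR-17-3p (fell by 3.01), miR-5701 (0 exosome reads, at least 60.2-fold) and the tRNA-like entries miR-1260a (fell by 4.73, SE 0.94) and miR-1260b (fell by 4.72, SE 0.94, adjusted p = 0.00885 for both). miR-4286 (-3.26), miR-7977 (-3.21), miR-615-3p (-3.11), miR-21-3p (-2.99, SE 0.71) and miR-19b-1-5p (0 exosome reads, at least 37.7-fold) completed the lower ones named by rank. Not every call held without 1 library: that of miR-451a (6.35, SE 1.33; 7.93 and 3.19) had a largest adjusted p of 0.0532 without SNU-719 cell replicate 1 or 2, that of miR-199a-3p and miR-199b-3p (merged; 5.71, SE 1.32; 7.04 and 3.05) 0.0736 without any of SNU-719 cell or exosome replicates 1 and 2, and those of miR-21-3p (at most 0.0825 over all settings), miR-615-3p (0.0991), miR-223-5p (0.251, with 1 cell read, ratio 233, interval 40.7 to 9315) and miR-7977 (0.0532) were also lost without single SNU-719 libraries. With only the 2 groups in the fit the calls of miR-1246 (adjusted p = 0.0601), miR-1290 (0.0852), miR-143-3p (0.067), miR-1260a and miR-1260b (0.0589), miR-19b-1-5p (0.0601) and miR-4286 (0.0762) were lost.

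Over all 760 tested miRNAs, limma called 78, of which 21 were higher and 57 lower in SNU-719 exosomes. At unadjusted p under 0.05 there were 210. All 78 changed the same way in replicates 1 and 2 and in replicate 3, and 69 of them by at least 2-fold in both. For all 78 the groups did not overlap, which by itself fixes the same direction in both, so that agreement is no separate support. The groups did not overlap for 237 miRNAs (31.2%, against 10% by chance). The number of calls depended on single libraries: it was 155 without AGS exosome replicate 3, 138 without SNU-719 exosome replicate 3, 49 without SNU-719 exosome replicate 2, 35 without SNU-719 cell replicate 1 and 33 without SNU-719 cell replicate 2, and it was 341 without replicate 3 in any group. Quantile normalization split the calls into 31 higher and 53 lower and edgeR into 38 and 36, so the surplus of lower miRNAs depended on the method.

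**Figure D1:**
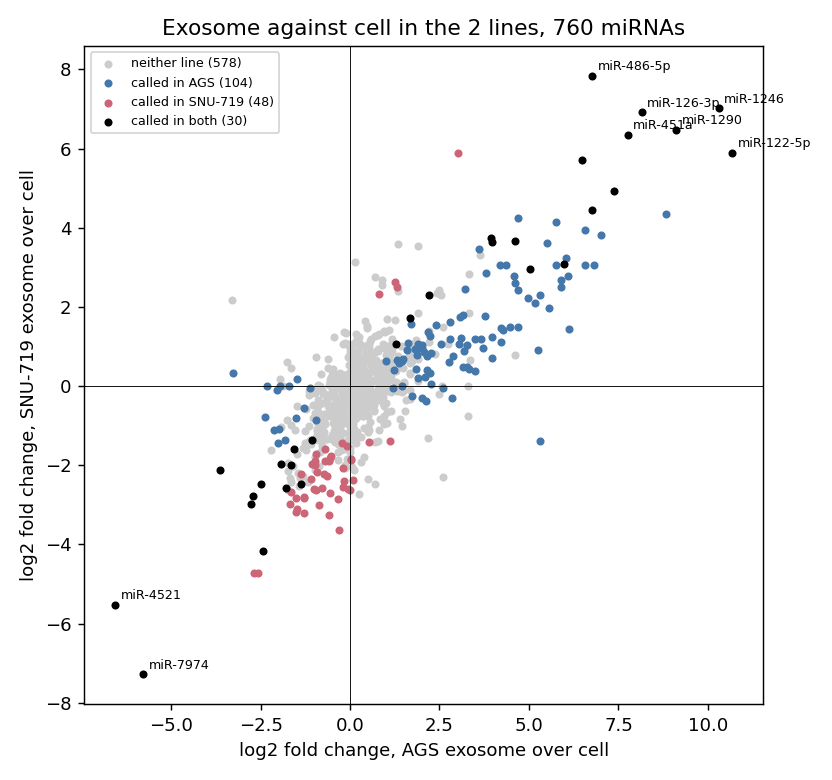
Log2 change from cells to exosomes in AGS (horizontal axis) and SNU-719 (vertical axis) for 760 miRNAs, 1 point each, coloured by the comparison in which the miRNA was called. Named points include miR-486-5p (7.84 in SNU-719, 6.77 in AGS), miR-122-5p (5.90 and 10.68) and miR-4521 (-5.53 and -6.56).

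Of the lists, blood, stromal, 14q32 and miR-320 miRNAs were shifted upward in SNU-719 exosomes at the preset correlation, and none at the estimated one. Of 10 erythroid and blood cell markers 4 rose (miR-451a, miR-486-5p, miR-223-3p, miR-223-5p), with a list median of 3.22 (3.78 in replicates 1 and 2, 1.66 in replicate 3, adjusted p = 0.00541, adjusted p = 0.729 with an estimated correlation); adjusted over the list alone, 6 rose and 1 fell. Of 8 stromal and smooth muscle markers 3 rose (miR-143-3p, miR-145-3p, miR-199a-3p with miR-199b-3p), with a median of 2.04 (2.41 and 1.36; 2.31 with 1 member of few reads left out, adjusted p = 0.00083, adjusted p = 0.729 with an estimated correlation), and 5 adjusted over the list alone. Of 35 members of the 14q32 cluster only miR-369-3p rose, also adjusted over the list alone, with a median of 0.79 (1.49 and 0.07, adjusted p = 0.00083, adjusted p = 0.801 with an estimated correlation). None of 5 miR-320 family members was called, 4 adjusted over the list alone, with a median of 1.49 (0.66 and 3.15, adjusted p = 0.0162, adjusted p = 0.729 with an estimated correlation). The miR-320 call was lost without SNU-719 exosome replicate 3 (adjusted p = 0.202). The blood call of miR-223-3p (3.65, SE 1.02) had adjusted p = 0.0404 and was lost without single libraries, with at most 0.186 over all settings, and with replicate number as a block (0.0544). The stromal call of miR-145-3p (2.31, SE 0.63, adjusted p = 0.0362, at most 0.349) and that of the endothelial miR-126-5p (2.96, SE 0.80, adjusted p = 0.0362, at most 0.366) were also lost without single libraries, but not with the block.

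The other 14 lists had adjusted p from 0.0817 (miR-99, miR-100 and miR-125 family, median 1.36, 1 up adjusted over the list alone) to 0.951 (miR-17-92 and paralogues, -0.05). Among 24 entries overlapping other RNAs 3 rose (miR-1246, miR-1290, miR-4508) and 7 fell (miR-7977, miR-1260a, miR-1260b, miR-4286, miR-4485-3p, miR-664a-3p, miR-12136), with 6 and 8 adjusted over the list alone (median 0.42, adjusted p = 0.944); the calls of miR-4508, miR-4485-3p, miR-664a-3p, miR-7977 and miR-12136 were lost with single libraries left out. The splicing-derived miR-484 fell by 2.21 (SE 0.45, adjusted p = 0.00911, 0.0601 at most without SNU-719 cell replicate 1 or 2 or with only the 2 groups in the fit) among mirtrons (-0.81, adjusted p = 0.152). miR-96-5p of the miR-183 cluster (0.17, adjusted p = 0.728) fell by 1.98 (SE 0.42, adjusted p = 0.011) and held in every setting. The remaining medians were -0.42 for the miR-200 family (2 fell, miR-141-5p and miR-200c-5p, both lost without single libraries and the latter with replicate number as a block, 0.0547, list adjusted p = 0.355), -0.43 for let-7 (0.533), 0.33 for gastrointestinal epithelium (0.588), -0.12 for HOX clusters (miR-615-3p fell; 0.882) and -0.70 for NF-kB and EBV induced miRNAs (miR-21-3p and miR-34a-5p fell; 0.728). They were -0.81 for the miR-34 family (miR-34a-5p fell; 0.423), -0.03 for C19MC and miR-371 (0.728), 0.43 for the Xq cluster (0.493) and 1.13 for muscle markers (1.63 with 1 member at its bound; 0.127). The call of miR-34a-5p (-2.46, SE 0.68, adjusted p = 0.0378) was lost without 8 of the 12 libraries, left out 1 at a time, and with edgeR (at most 0.106). Median, mean and test differed in sign for the HOX list (-0.12, -0.03, up), C19MC and miR-371 (-0.03, 0.08, up) and the miR-183 cluster (0.17, -0.49, down). Of markers too few for a test, the liver list held miR-122-5p, the endothelial list miR-126-3p and miR-126-5p, all called, and the neural list miR-128-3p (-0.96, not called) and miR-338-3p.

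**Figure D2:**
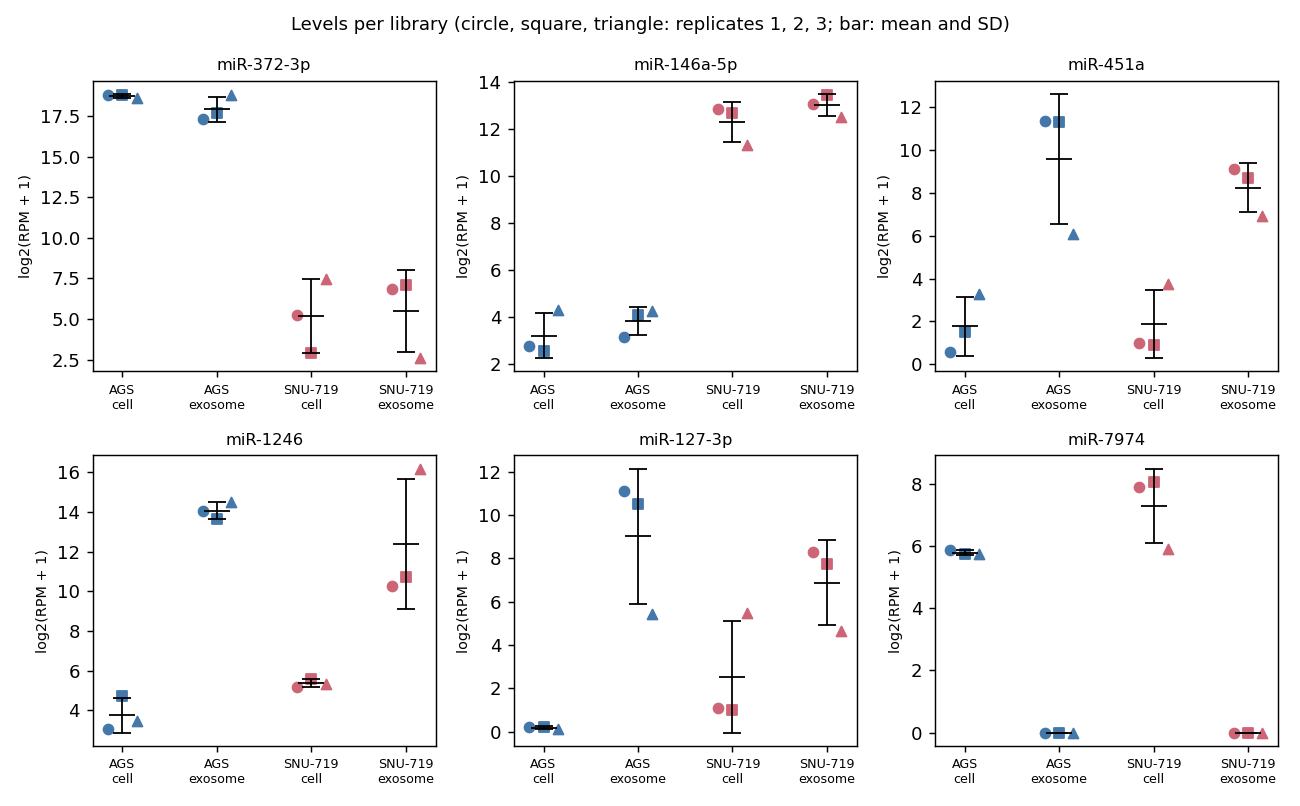
Levels of miR-372-3p, miR-146a-5p, miR-451a, miR-1246, miR-127-3p and miR-7974 as log2(RPM + 1) in the 3 libraries of each group; circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean and SD. miR-451a, for example, had 0.48, 1.88 and 8.68 RPM in AGS cells and 2544, 2496 and 65.57 RPM in AGS exosomes.

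The viral miRNAs of SNU-719, processed from the BART and BHRF1 transcripts of EBV, were as plentiful in exosomes as in cells relative to human miRNAs, within the spread of the libraries. There were 33.5 EBV reads per 100 human reads in cells (SD 1.20, n = 3) and 36.7 in exosomes (SD 11.97, n = 3), a log2 change of 0.07 (1.05-fold, exact two-sided p = 1). By library the load was 33.28, 34.81 and 32.46 in cells and 41.42, 45.53 and 23.05 in exosomes, so it was higher in exosomes by 0.32 and 0.39 on the log2 scale in replicates 1 and 2 and lower in replicate 3 (-0.49). The EBV-negative AGS libraries held 0.00055 to 0.00484 EBV reads per 100 human reads. The load of SNU-719 was thereby 44290-fold higher than that of AGS in cells and 15960-fold in exosomes (exact two-sided p = 0.1 each).

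**Figure D3:**
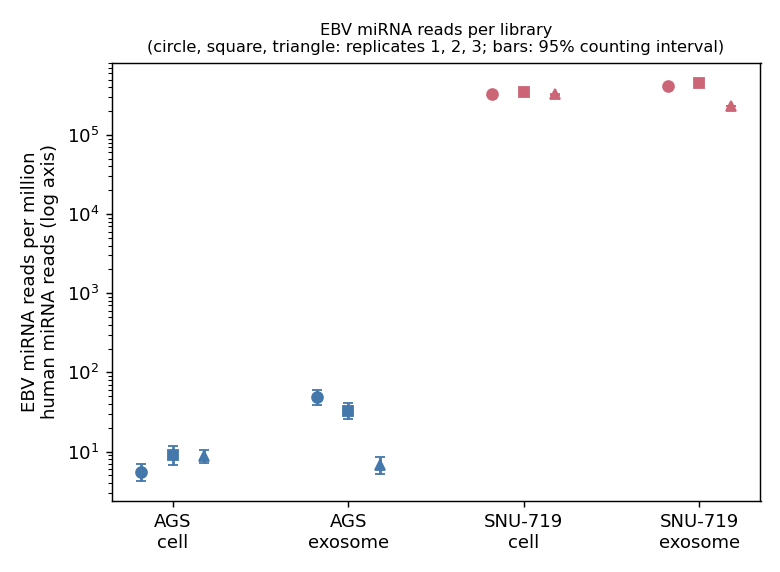
EBV miRNA reads relative to 1000000 human miRNA reads in each of the 12 libraries on a log axis, by group, with 95% counting intervals. SNU-719 libraries held 2493459 to 4283338 EBV reads in cells and 443270 to 1892137 in exosomes.

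Among EBV miRNAs, 5 of 43 tested had a smaller share of EBV reads in SNU-719 exosomes than in cells and none a larger one (limma, adjusted p under 0.05; 13 at unadjusted p under 0.05). edgeR called 3 lower and 1 higher, miR-BART2-3p (1.94, adjusted p = 0.0466; limma 1.29, SE 0.60, adjusted p = 0.163). miR-BART17-3p of BART cluster 1 fell by 4.02 (SE 0.49; -4.01 in replicates 1 and 2, -4.04 in replicate 3, adjusted p = 0.000171), from 1.20% of EBV reads (SD 0.354) to 0.0745% (SD 0.0238). The other 4 belong to BART cluster 2. miR-BART10-5p fell by 3.96 (SE 0.70; -4.66 and -2.54, adjusted p = 0.00196), and miR-BART18-5p by 2.63 (SE 0.46; -2.75 and -2.40, adjusted p = 0.00196), from 1.03 to 0.162% of EBV reads. miR-BART9-3p fell by 1.62 (SE 0.46; -1.92 and -1.04, adjusted p = 0.0392), from 4.58% (SD 0.281) to 1.58% (SD 0.70), and miR-BART14-5p by 1.95 (SE 0.51; -1.95 and -1.96, adjusted p = 0.0296). miR-BART17-3p, miR-BART10-5p and miR-BART18-5p were called in every setting; the calls of miR-BART14-5p (adjusted p at most 0.196) and miR-BART9-3p (at most 0.209) were lost with edgeR and without SNU-719 cell replicate 1 or 2 or exosome replicate 1 or 2, and the latter also without cell replicate 3. With replicate number as a block, 9 were called, adding miR-BART5-5p (adjusted p = 0.0474), miR-BART1-3p (0.0184), miR-BART22 (0.0394) and miR-BART6-5p (0.00395), chosen after their values were seen. The count was 3 without SNU-719 cell replicate 1, cell replicate 2 or exosome replicate 1, and 26 without SNU-719 exosome replicate 3 (2 higher, 24 lower). With a term for the third replicates it was 13, and without replicate 3 in any group 33. Shares of EBV reads add up to a fixed total. miR-BART1-5p held 43.4 and 44.3% in exosome replicates 1 and 2, against 16.7 and 17.1% in cell replicates 1 and 2. This alone lowers the shares of the others, so the many lower shares without replicate 3 need not be lower levels relative to human reads.

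The viral miRNA with the highest mean share was miR-BART1-5p, with 16.1% of EBV reads in cells (SD 1.42) and 33.3% in exosomes (SD 18.2; log2 change 0.84, SE 0.59; 1.38 and -0.23, adjusted p = 0.376). Its share in exosomes was 43.4, 44.3 and 12.3% in replicates 1 to 3, against 16.7, 17.1 and 14.4% in cells. In the third replicates others stood above it, miR-BART16 in cells (15.5%) and miR-BART10-3p in exosomes (31.3%). miR-BART22 made up 13.9% in cells (SD 0.91) and 5.66% in exosomes (SD 4.07, adjusted p = 0.149), and miR-BART10-3p 9.42 and 14.5% (SD 14.7). By list, BART cluster 1 held 38.5% of EBV reads in cells (SD 3.21) and 48.9% in exosomes (SD 16.8), and BART cluster 2 58.4% (SD 3.86) and 48.7% (SD 14.8, exact two-sided p = 0.4 each). BART2, outside both clusters, held 3.08% (SD 0.713) and 2.38% (SD 1.95, exact two-sided p = 0.6), and the BHRF1 miRNAs, which belong to the lytic and growth programmes, 491 reads in all (exact two-sided p = 0.6; all adjusted p = 0.6). In cluster 1 1 of 14 tested miRNAs fell (2 adjusted over the list alone), in cluster 2 4 of 24 (4), and of BART2 (2 tested) and BHRF1 (3 tested) none. Of the 43, 23 changed the same way in replicates 1 and 2 and in replicate 3, and for 14 (32.6%, against 10% by chance) the groups did not overlap.

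**Figure D4:**
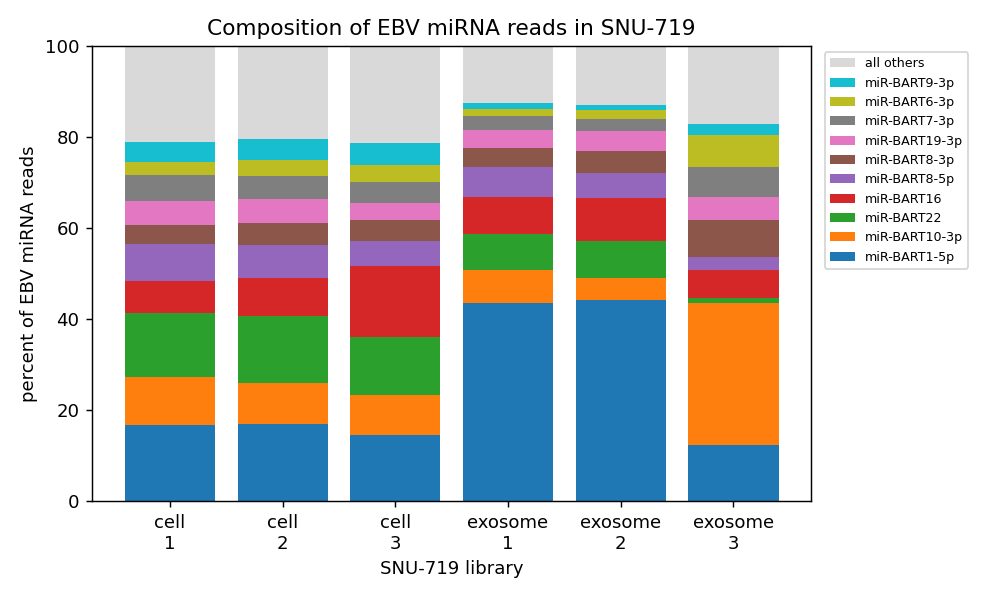
Percent of EBV reads held by the 10 most abundant EBV miRNAs and by all others, stacked, in the 3 cell and 3 exosome libraries of SNU-719. miR-BART1-5p held 43.4, 44.3 and 12.3% of EBV reads in exosome replicates 1 to 3.

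AGS exosomes were likewise richer than their cells in liver, blood, vessel and 14q32 miRNAs, and most called miRNAs were higher in exosomes. miR-122-5p rose by 10.68 (SE 0.72; 11.67 in replicates 1 and 2, 8.70 in replicate 3, adjusted p = 1.75e-06), from 1.14 RPM (SD 0.98) to 3887 RPM (SD 2214). miR-1246 rose by 10.31 (SE 1.18; 9.95 and 11.03, adjusted p = 0.000193) and miR-1290 by 9.11 (SE 1.26). miR-127-3p, from the imprinted 14q32 region opposite RTL1 (chromosome 14, 100882979 to 100883075, plus strand), rose by 8.84 (SE 1.54; 10.59 and 5.33, adjusted p = 0.00269). The red cell miRNA miR-451a, on chromosome 17 (28861369 to 28861440, minus strand), rose by 7.76 (SE 1.33; 10.25 and 2.78, adjusted p = 0.00248).

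miR-126-3p rose by 8.15 (SE 1.15; 10.37 and 3.71), miR-369-3p by 5.98 (SE 0.52; 5.77 and 6.41, adjusted p = 1.47e-05), miR-10b-5p by 6.08 (SE 0.95; 7.83 and 2.58, adjusted p = 0.00156) and the blood cell miR-142-5p by 5.25 (SE 0.76; 6.85 and 2.05, adjusted p = 0.000932). miR-6529-5p had 0 cell reads (at least 1256-fold) and miR-412-5p, from an intron of MEG9 (chromosome 14, 101065447 to 101065537, plus strand), 1 cell read (ratio 2989, interval 536 to 118152). In the other direction miR-4521 fell by 6.56 (SE 0.80), miR-7974 had 0 exosome reads (at least 243-fold less), and miR-4455 had 2 (ratio 90.5, interval 24.9 to 749). These calls held in every setting. With only the 2 groups in the fit, the calls of miR-379-5p (7.02, SE 1.37; 9.06 and 2.93, adjusted p = 0.0582), miR-409-3p (6.57, SE 1.35; 0.0777) and miR-486-5p (6.77, SE 1.47; 9.81 and 0.68, adjusted p = 0.00889, then 0.0872) were lost. miR-486-5p stood at 78.9 RPM in cells (SD 85.9) and 19005 RPM in exosomes (SD 18622). The calls of miR-493-5p (3 cell reads, ratio 2067, interval 706 to 10028) and of miR-205-5p (-3.28, SE 0.90), miR-34a-5p (-2.48, SE 0.68), miR-135b-3p (-2.12), miR-93-3p (-1.97), miR-96-5p (-1.65, SE 0.42), miR-374b-5p (-1.57), miR-373-5p (-1.49) and miR-23b-3p (-1.29) were each lost without at least 3 of the 6 AGS libraries, left out 1 at a time, with adjusted p up to 0.308 over all settings.

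limma called 134 of 760 miRNAs, 106 higher and 28 lower in AGS exosomes (228 at unadjusted p under 0.05). In replicates 1 and 2 and in replicate 3 131 of them changed the same way, 90 by at least 2-fold in both. For 130 of the 134 called the groups did not overlap, which by itself fixes the same direction in both. Over all tested miRNAs the groups did not overlap for 264 (34.7%, against 10% by chance). Scaling shifted the split: with median-of-ratios scaling 93 were higher and 58 lower, with quantile normalization 83 and 82, and with edgeR 81 and 56. Without AGS exosome replicate 3 207 were called, without AGS exosome replicate 1 60, without AGS cell replicate 2 61, without AGS cell replicate 1 63 and without AGS exosome replicate 2 70; without replicate 3 in any group it was 368.

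All 35 tested members of the 14q32 cluster had positive changes in AGS exosomes, and 22 rose (32 adjusted over the list alone). The list median was 3.30 (4.41 in replicates 1 and 2, 0.88 in replicate 3; 4.62 with 8 members at their bound, adjusted p = 1.48e-12, adjusted p = 0.49 with an estimated correlation). In every setting 7 of these calls held, those of miR-127-3p, miR-299-3p, miR-369-3p, miR-381-3p, miR-410-3p, miR-495-3p and miR-656-3p. Together the cluster summed to 7605, 5495 and 252.8 RPM in AGS exosomes against 5.60, 6.81 and 7.95 RPM in the cells. Whether these exosome reads came from the AGS cells was not tested. Of 10 blood cell markers 8 rose (9 adjusted over the list alone), among them miR-142-5p and miR-451a, with a median of 4.93 (6.62 and 1.23, adjusted p = 2.43e-05, adjusted p = 0.49 with an estimated correlation). The blood calls of miR-150-5p (5.31, SE 1.503; 7.76 and 0.39), miR-223-3p (3.97; 6.003 and -0.09) and miR-144-5p, and the stromal ones of miR-145-3p and miR-199a-5p were lost with single libraries left out. All 5 members of the miR-320 family rose, also adjusted over the list alone, with a median of 3.50 (3.53 and 3.77, adjusted p = 8.6e-05, adjusted p = 0.49 with an estimated correlation). miR-320b rose by 3.50 (SE 0.48; 3.53 and 3.45, adjusted p = 0.000845) and miR-320d by 5.18 (SE 0.84; 5.13 and 5.27, adjusted p = 0.00164). miR-320a-3p rose by 2.27 (SE 0.34; 2.49 and 1.83, adjusted p = 0.0011), which edgeR did not call (adjusted p = 0.0809). The call of miR-320e was lost without 5 of the 6 AGS libraries, left out 1 at a time, and with edgeR, quantile normalization or a pseudocount of 10 RPM (adjusted p at most 0.133). Of 8 stromal markers 4 rose (miR-145-3p, miR-199a-5p, miR-199a-3p with miR-199b-3p, miR-214-3p; 6 adjusted over the list alone), with a median of 3.32 (4.29 and 0.62, adjusted p = 0.00252, adjusted p = 0.49 with an estimated correlation). The C19MC and miR-371 list, on chromosome 19, was shifted downward with a median of -0.57 (-0.90 and 0.02, adjusted p = 0.00224, adjusted p = 0.49 with an estimated correlation). Of its 16 members 3 fell, also adjusted over the list alone, the placental miR-517a-3p with miR-517b-3p, miR-519a-3p and miR-526b-5p; each call was lost with single libraries left out (adjusted p at most 0.118, 0.158 and 0.167 over all settings).

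The other 13 lists had adjusted p from 0.103 to 0.566. Lowest of them were the muscle markers (median 1.75, 3.30 with 2 members at their bound; miR-1-3p and miR-133a-3p rose, 3 adjusted over the list alone, both lost without AGS exosome replicate 1). Of the miR-99, miR-100 and miR-125 family 3 rose (miR-99a-5p, miR-100-5p, miR-125b-5p; median 3.06, 4.59 in replicates 1 and 2 and -0.66 in replicate 3, adjusted p = 0.381), each lost without AGS exosome replicate 1 or 2. Of the HOX list 2 rose (miR-10b-5p and miR-10b-3p, 4 adjusted over the list alone; median 1.47, adjusted p = 0.381), and of gastrointestinal epithelium 3 rose (miR-215-5p, miR-375-3p, miR-148a-3p) and miR-205-5p fell (median 0.75, adjusted p = 0.566). The call of miR-148a-3p (1.38) was lost with median-of-ratios scaling, and that of miR-375-3p (1.22) with 14 other settings. Of entries overlapping other RNAs 4 rose (miR-1246, miR-1290, miR-4488, miR-4516, the last 2 lost with single libraries left out; median 0.72, adjusted p = 0.566), and of miR-17-92 and paralogues 2 (miR-363-3p, miR-25-3p; 0.43, adjusted p = 0.456). In the NF-kB and EBV induced list (0.02, adjusted p = 0.456) miR-155-5p rose by 4.37 (SE 1.13; 6.32 and 0.47; lost with single libraries left out, adjusted p at most 0.099). let-7b-5p rose by 1.21 among let-7 miRNAs (0.50, adjusted p = 0.566), a call lost with other scaling, and miR-1226-5p rose among mirtrons (-0.60, adjusted p = 0.211), lost with single libraries left out like miR-10b-3p. The miR-34 family (-0.60, adjusted p = 0.244), the miR-200 family (-0.08, adjusted p = 0.381), the Xq cluster (0.04) and the miR-183 cluster (0.00) had no other call. The neural miR-128-3p (0.94) was not called. Median, mean and test differed in sign for NF-kB and EBV induced miRNAs (0.02, 0.09, down) and the Xq cluster (0.04, -0.16, down).

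The exosome-to-cell changes of the 2 lines resembled each other. Called in both were 17 higher miRNAs (2.9 expected by chance), among them miR-122-5p, miR-126-3p, miR-126-5p, miR-451a, miR-486-5p, miR-1246, miR-1290, miR-369-3p, miR-412-5p and miR-6529-5p. Also called in both were 13 lower ones (2.1 expected), among them miR-7974, miR-4521, miR-4455, miR-5701, miR-96-5p and miR-34a-5p. None was called in opposite directions, and the changes correlated at 0.767 over 760 miRNAs, which are not independent replicates and share no library between the lines. The expected numbers take the calls as independent. Yet 1 fit gives each miRNA the same estimate of spread in both lines, which alone can raise the overlap. The interaction, by contrast, had 0 calls (limma; 91 at unadjusted p under 0.05; 0 with edgeR; smallest adjusted p = 0.125). The liver miR-122-5p had an interaction of -4.79 (SE 1.013, adjusted p = 0.125), and miR-150-5p -6.70 (SE 2.13, adjusted p = 0.23). The count was 88 without AGS exosome replicate 3 (6 higher, 82 lower), 26 without SNU-719 exosome replicate 3 (6 higher, 20 lower) and 286 without replicate 3 in any group.

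At the preset correlation 4 lists were called for the interaction, and none at the estimated one. The interaction median was -2.69 for 14q32 (-3.35 in replicates 1 and 2, -1.04 in replicate 3, adjusted p = 8.69e-07, adjusted p = 0.94 with an estimated correlation; 0 members called, also adjusted over the list alone). It was -2.31 for the miR-320 family (-2.90 and -0.59, adjusted p = 0.0046, adjusted p = 0.94 with an estimated correlation; 4 lower adjusted over the list alone), lost without AGS exosome replicate 3 (adjusted p = 0.146). It was 0.84 for C19MC and miR-371 (1.42 and -0.45, adjusted p = 2.45e-06, adjusted p = 0.563 with an estimated correlation). In SNU-719 8 of the 16 members had too few reads to be given a change and 1 stood at its bound, so this value mostly restates the AGS median of -0.57 with its sign turned and is no measured difference between the lines. It was 0.25 for the Xq cluster (-0.47 and 2.10, adjusted p = 0.0276, adjusted p = 0.94 with an estimated correlation), lost without any of the third libraries of the 4 groups (adjusted p up to 0.377). The blood markers, with a median of -1.51 (adjusted p = 0.176; 3 lower adjusted over the list alone), were called without AGS exosome replicate 3 (adjusted p = 0.00157) or SNU-719 exosome replicate 1 (0.0477) or with median-of-ratios scaling (0.0197). The list of miR-17-92 and paralogues (adjusted p = 0.619) was called without SNU-719 cell replicate 3 (0.00448). Both had adjusted p = 0.948 with an estimated correlation. The other 12 lists had adjusted p from 0.385 to 0.943. Median and test differed in sign for gastrointestinal epithelium (-0.55, up), NF-kB and EBV induced miRNAs (-0.58, up), stromal markers (-0.31, up), the miR-99, miR-100 and miR-125 family (-0.46, up) and the miR-183 cluster (-0.15, up), and median and mean for the miR-34 family (0.01, -0.22). No list was called with fry.

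On the log2(RPM + 1) scale, the largest decreases in SNU-719 cells against AGS cells were those of the miR-371 to miR-373 locus on chromosome 19. miR-372-3p, expressed in embryonic stem cells from chromosome 19 (53787890 to 53787956, plus strand), fell by 13.54 (SE 1.19, adjusted p = 3.75e-06) to 72.5 RPM (SD 89.4). Its neighbours miR-371a-5p (53787675 to 53787741) and miR-373-3p (53788705 to 53788773) fell by 12.80 (SE 1.03) and 12.56 (SE 0.68). In SNU-719 cells miR-372-3p had 36.9, 6.34 and 174.16 RPM. Whether these few reads came from the SNU-719 cells themselves was not tested, so the size of the changes of this locus is uncertain. miR-99b-5p and miR-125a-5p, from introns of SPACA6 on the same chromosome (51692612 to 51692681 and 51693254 to 51693339, plus strand), also fell, by 10.18 (SE 0.63) and 9.79 (SE 0.82). Higher in SNU-719 was above all miR-146a-5p, induced by NF-kB and encoded in an exon of MIR3142HG on chromosome 5 (160485352 to 160485450, plus strand), which rose by 9.09 (SE 0.58), from 9.80 RPM (SD 7.80) to 5574 RPM (SD 2658).

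The changes were -14.73 in replicates 1 and 2 and -11.15 in replicate 3 for miR-372-3p, and 10.14 and 7.01 for miR-146a-5p. Also lower were miR-371a-3p (fell by 12.11, SE 0.80), miR-99b-3p (fell by 9.02), let-7e-5p of the SPACA6 locus (fell by 5.96, SE 0.63), the squamous epithelial miR-205-5p on chromosome 1 (fell by 9.26, SE 0.90, adjusted p = 8.98e-06) and miR-302a-5p of the stem cell cluster on chromosome 4 (fell by 8.89). miR-372-5p (2 SNU-719 reads, ratio 15574, interval 4311 to 128606), miR-302b-3p (3 reads, ratio 11713, interval 4008 to 56799) and miR-373-5p (3 reads, ratio 6409.8, interval 2193 to 31084) were lower too. Higher in SNU-719 were miR-196b-5p, in an exon of HOXA9 on chromosome 7 (27169480 to 27169563, minus strand; rose by 8.95, SE 0.58), and miR-338-5p, in an intron of AATK on chromosome 17 (rose by 7.37, SE 0.59; miR-338-3p had 2 AGS reads, ratio 2122, interval 587 to 17525). The blood cell miRNAs miR-150-5p (6.43, SE 1.503, adjusted p = 0.00789), miR-142-3p (5.32) and miR-142-5p (5.28, SE 0.76) rose as well. So did the intestinal miR-194-5p (5.29, SE 0.73; from 2439 RPM, SD 1741, to 67825 RPM, SD 9302) and miR-215-5p (5.04, SE 0.60), as well as miR-105-5p of chromosome X (5.45), miR-549a-3p (5.14) and miR-1269a (2 AGS reads, ratio 1496, interval 414 to 12362). The calls of all 24 held in every setting.

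limma called 173 miRNAs, 115 higher and 58 lower in SNU-719 cells (266 at unadjusted p under 0.05). All 173 changed the same way in replicates 1 and 2 and in replicate 3, 152 by at least 2-fold in both. For 172 of the 173 the groups did not overlap, which by itself fixes the same direction in both. Over all tested miRNAs the groups did not overlap for 390 (51.3%, against 10% by chance). The surplus of higher miRNAs depended on scaling. The median change over 760 miRNAs was 0.49 with RPM and 0.02 with median-of-ratios scaling, which gave 57 higher and 81 lower, quantile normalization gave 71 and 77, and edgeR 57 and 90. The same scaling moved the median from 0.21 to -0.07 for AGS exosomes against cells, from -0.11 to -0.24 for exosomes of both lines and from -0.56 to -0.06 for the interaction. With only the 2 groups in the fit 299 were called, and without replicate 3 in any group 360.

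The C19MC and miR-371 list was the only one that passed with both correlations. Of its 16 members 13 fell (15 adjusted over the list alone), including the placental miR-516a-5p (fell by 5.37, SE 0.56, adjusted p = 1.45e-05) and miR-512-3p (fell by 3.70), with a median of -2.39 (-3.05 and -1.15; -3.57 with 3 members at their bound, adjusted p = 1.46e-16, adjusted p = 0.0396 with an estimated correlation). The calls of miR-516b-5p, miR-517a-3p with miR-517b-3p, miR-518b and miR-520f-3p were lost with single libraries left out. Of 9 gastrointestinal epithelium miRNAs 6 rose (miR-192-5p, miR-194-5p, miR-215-5p, miR-375-3p, miR-148a-3p, miR-203a-3p) and miR-205-5p fell, with a median of 2.88 (3.12 and 2.41, adjusted p = 0.0367, adjusted p = 0.274 with an estimated correlation). The stomach and islet miRNA miR-375-3p rose by 4.95 (SE 0.37; 4.92 and 5.01, adjusted p = 9.9e-07), miR-192-5p by 4.69 (SE 0.56; 3.73 and 6.60, adjusted p = 4.8e-05) and miR-148a-3p by 2.88 (SE 0.29; 3.12 and 2.41, adjusted p = 1.01e-05). The list call was lost with replicate number as a block (adjusted p = 0.122), without SNU-719 cell replicate 3 (0.0911) and without AGS exosome replicate 3 (0.0641). Of 13 miRNAs of miR-17-92 and paralogues 4 rose (miR-92a-3p by 2.10, SE 0.44, miR-106b-5p, miR-93-5p and miR-25-3p; 6 adjusted over the list alone), with a median of 1.97 (2.46 and 0.47, adjusted p = 0.0367, adjusted p = 0.742 with an estimated correlation). The calls of miR-92a-3p, miR-93-5p and miR-25-3p were lost with median-of-ratios scaling, and the list call without SNU-719 cell replicate 1 (adjusted p = 0.144), SNU-719 cell replicate 2 (0.101), AGS cell replicate 3 (0.0758) or AGS exosome replicate 3 (0.0604).

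Lower in SNU-719 cells were the Xq cluster (1 of 7 fell, miR-509-3-5p, 3 adjusted over the list alone; median -1.54, -1.16 and -2.15, adjusted p = 0.00219, adjusted p = 0.363 with an estimated correlation) and the miR-99, miR-100 and miR-125 family. Of this family 2 of 5 fell (miR-99b-5p and miR-125a-5p), with a median of -1.71 (-1.20 and -2.73, adjusted p = 0.00219, adjusted p = 0.363 with an estimated correlation). Of 8 stromal markers miR-143-3p (fell by 5.74, adjusted p = 0.00174) and miR-145-5p fell, 4 adjusted over the list alone, with a median of -1.62 (-1.55 and -1.74; -2.10 with 1 member at its bound and 1 left out, adjusted p = 0.00458, adjusted p = 0.512 with an estimated correlation). The epithelial miR-200 family had an adjusted p of 0.05 (median 1.30), which was 0.0486 with replicate number as a block (adjusted p = 0.274 with an estimated correlation); miR-200a-3p (2.23), miR-200b-3p (1.30, SE 0.29) and miR-141-3p rose, 6 members adjusted over the list alone, and all 3 calls were lost with median-of-ratios scaling.

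The other 11 lists had adjusted p from 0.21 to 0.781. Medians were 1.71 for the miR-320 family (3 rose, all lost with median-of-ratios scaling; 0.21), 0.62 for HOX clusters (miR-196a-5p and miR-196b-5p rose; 0.266), 1.17 for the miR-183 cluster (miR-96-5p rose; 0.266) and 0.89 for mirtrons (miR-484 rose; 0.436). They were 0.92 for entries overlapping other RNAs (5 rose, miR-1260a, miR-1260b, miR-4286, miR-1285-3p and miR-12136; 0.454), 0.91 for 14q32 (0.632), 0.91 for NF-kB and EBV induced miRNAs (miR-146a-5p, miR-34a-5p and miR-222-3p rose, miR-9-3p fell; 0.688) and 0.09 for blood markers (miR-142-3p, miR-142-5p and miR-150-5p rose; 0.688). They were 1.35 for the miR-34 family (miR-34a-5p rose by 2.46, SE 0.68; 0.722), 0.00 for muscle markers (0.722) and 0.70 for let-7 (let-7g-5p rose, let-7e-5p fell; 0.781). Of the calls outside the named ranks, those of miR-34a-5p, miR-222-3p, let-7g-5p, miR-96-5p, miR-203a-3p and the 5 entries overlapping other RNAs were lost with median-of-ratios scaling. The 14q32 list was called with that scaling (adjusted p = 0.0369, adjusted p = 0.903 with RPM and an estimated correlation). With it the medians of NF-kB and EBV induced miRNAs (-0.01), let-7 (-0.23) and blood markers (-0.15) turned negative. No other median of these 11 lists turned its sign. Median, mean and test differed in sign for let-7 (0.70, -0.09, down) and muscle markers (0.00, 0.25, down).

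The exosomes of the lines differed much as their cells did. miR-372-3p fell by 12.42 in SNU-719 exosomes relative to AGS exosomes (SE 1.19; -10.52 in replicates 1 and 2, -16.20 in replicate 3, adjusted p = 9.21e-06), miR-371a-5p fell by 12.21, miR-373-3p fell by 11.76 and miR-371a-3p fell by 11.23. In SNU-719 exosomes miR-372-3p had 114, 133.52 and 5 RPM, reads whose source was likewise not tested. Of the SPACA6 locus miR-99b-5p fell by 8.66, miR-125a-5p by 7.66 and let-7e-5p by 5.29 (SE 0.63). miR-146a-5p rose by 9.21 (SE 0.58; 9.67 and 8.30), miR-196b-5p by 7.36 and miR-194-5p by 4.64. The liver miR-122-5p, without a call between the cells, fell by 4.58 (SE 0.72; -5.30 and -3.14, adjusted p = 0.000649).

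Also lower in SNU-719 exosomes were miR-99b-3p (fell by 8.65), miR-125a-3p (fell by 7.88), miR-302b-3p (0 SNU-719 reads, at least 1326-fold), miR-302a-5p (2 reads, ratio 4366, interval 1208 to 36052), miR-372-5p (3 reads, ratio 3449.9, interval 1180.2 to 16731) and miR-373-5p (1 read, ratio 2006, interval 359.8 to 79279). Also higher were miR-549a-3p (6.38), miR-1269a (6.35), miR-338-5p (6.33), miR-105-5p (4.97), miR-767-5p (4.28), miR-338-3p (3 AGS reads, ratio 217, interval 73.9 to 1056) and miR-549a-5p (0 AGS reads, at least 57.6-fold). miR-365b-5p rose by 5.25 (SE 0.98, adjusted p = 0.00237), a call lost with only the 2 groups in the fit (adjusted p = 0.0725); the other 23 miRNAs named by rank were called in every setting.

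limma called 138 miRNAs, 68 higher and 70 lower (237 at unadjusted p under 0.05). All 138 changed the same way in replicates 1 and 2 and in replicate 3, 110 by at least 2-fold in both. For 135 of the 138 the groups did not overlap, which by itself fixes the same direction in both. Over all tested miRNAs the groups did not overlap for 202 (26.6%, against 10% by chance). Quantile normalization gave 89 higher and 59 lower, and edgeR 43 and 50. Without AGS exosome replicate 3 264 were called, without AGS exosome replicate 2 88, with only the 2 groups in the fit 69, and without replicate 3 in any group 421. Called both between cells and between exosomes were 52 higher (10.3 expected by chance) and 42 lower miRNAs (5.3 expected), none in opposite directions, and the changes correlated at 0.844 over the 760 miRNAs. These expected numbers also take the calls as independent, although 1 fit gives each miRNA the same estimate of spread in both comparisons.

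Of the 16 C19MC and miR-371 members 8 were lower in SNU-719 exosomes (8 adjusted over the list alone; median -1.54, -1.80 and -1.75; -2.58 with 6 members at their bound, adjusted p = 7.46e-07, adjusted p = 0.214 with an estimated correlation), of which the call of miR-512-3p was lost with single libraries left out. Of gastrointestinal epithelium 6 of 9 rose and miR-205-5p fell (6 and 2 adjusted over the list alone; median 2.08, 1.97 and 2.29, adjusted p = 0.00466, adjusted p = 0.214 with an estimated correlation). Examples were miR-375-3p (4.14, SE 0.37, adjusted p = 6.23e-06), miR-192-5p (4.14, SE 0.56; 3.67 and 5.09, adjusted p = 0.000184) and miR-148a-3p (2.08, SE 0.29, adjusted p = 0.000214). The call of miR-203a-3p was lost in 15 of 25 settings (adjusted p at most 0.272). The 14q32 list was shifted downward with only miR-369-3p called, itself lost without SNU-719 exosome replicate 1 (none adjusted over the list alone; median -1.61, -2.69 and 0.91, adjusted p = 0.00204, adjusted p = 0.743 with an estimated correlation), a list call lost without AGS exosome replicate 1 (adjusted p = 0.0598). The miR-99, miR-100 and miR-125 family was shifted downward with 2 members called (4 adjusted over the list alone; median -2.94, -4.63 and -0.98, adjusted p = 0.00204, adjusted p = 0.387 with an estimated correlation). Of 8 stromal markers 3 fell (miR-143-5p, miR-145-5p, miR-214-3p; 6 adjusted over the list alone; median -2.29, -2.82 and -1.22, adjusted p = 0.00937, adjusted p = 0.616 with an estimated correlation), and these 3 calls were lost without AGS exosome replicate 1, as the list call was without SNU-719 exosome replicate 3 (adjusted p = 0.0533). With replicate number as a block the miR-200 family (median 0.94) went from adjusted p = 0.069 to 0.0454 and miR-17-92 and paralogues (1.07) from 0.08 to 0.0454 (adjusted p = 0.273 and 0.743 with an estimated correlation). Of these lists miR-200b-3p, miR-20a-5p and miR-93-5p rose and miR-363-3p fell, calls that edgeR did not make.

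The other 11 lists had adjusted p from 0.0834 (miR-183 cluster, median 1.20, all 3 up adjusted over the list alone) to 0.855 (entries overlapping other RNAs, -0.32, with miR-4454 and miR-1285-3p up and miR-4485-3p down). Medians were -1.30 for the Xq cluster (miR-509-3-5p fell, adjusted p = 0.194), -0.84 for let-7 (let-7e-5p fell, 0.208), 0.61 for mirtrons (miR-484 rose, 0.445), -0.21 for HOX clusters (miR-196a-5p and miR-196b-5p rose, 0.456) and 0.39 for the miR-34 family (miR-34a-5p rose, 0.456). They were -0.61 for the miR-320 family (0.456), -0.17 for NF-kB and EBV induced miRNAs (miR-146a-5p and miR-34a-5p rose, miR-9-5p fell, 0.456), -1.22 for blood markers and -0.72 for muscle markers (0.599 each). Of these calls only those of let-7e-5p, miR-146a-5p, miR-196a-5p and miR-196b-5p held without each single library and with edgeR. Median, mean and test differed in sign for HOX clusters (-0.21, 0.93, up), NF-kB and EBV induced miRNAs (-0.17, 0.61, up) and entries overlapping other RNAs (-0.32, 0.01, up).

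Exosome libraries of AGS held more miRNAs at 1 RPM or above than the cells: 618 (SD 62.4) against 505 (SD 6.81, exact two-sided p = 0.1, the smallest possible). Counting any value above 0, exosomes held fewer than cells: 873 against 1042.3 in AGS and 848.33 against 1126.3 in SNU-719 (exact two-sided p = 0.3 each). After thinning every library to 996122 reads, counted without merging, AGS exosomes held 704 (SD 10.8) and AGS cells 633 (SD 14.5, exact two-sided p = 0.1, adjusted p = 0.2). At 1 RPM or above, SNU-719 exosomes held 617 (SD 65.9) and SNU-719 cells 564 (SD 25.9, exact two-sided p = 0.3), and after thinning 718 (SD 13.7) and 710 (SD 16.5, exact two-sided p = 0.6). Between the lines, cells had exact two-sided p = 0.1 and exosomes exact two-sided p = 1.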

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

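Of the tests in this part, the splits of the libraries and the list tests with camera (both correlations) and fry were set before the results were seen. All others, among them the list test without each library, were chosen after.

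In AGS and SNU-719, the third exosome libraries stood apart from replicates 1 and 2, which raises the question whether depth, admixed cell RNA or a shared library batch could account for it. Depth goes with the replicate number in the exosomes (9210955 and 8207548 reads, against 996122 to 2470752). Of abundant miRNAs (at least 1000 RPM), 86 differed at least 2-fold after thinning to 996122 reads, against 88 before. miRNAs that abundant cannot be moved by thinning, so this count alone decides nothing. Between replicate 3 and replicates 1 and 2, chi-square per degree of freedom was 4237 and 3787 in AGS exosomes. In SNU-719 exosomes it was 2143 and 2824. These values argue against counting noise from fewer reads as the cause, for abundant miRNAs. Whether anything else that goes with depth could account for the pattern stays undecided. A mixture of exosome and cell RNA could not account for all of it, since at least 27.6% of abundant miRNAs (24 of 87 in AGS, 31.8% of 88 in SNU-719) lay over 1.5-fold outside the range spanned by cells and replicates 1 and 2, such as miR-27a-3p in AGS (14460 RPM, against 2851 to 5962) and miR-1246 in SNU-719 (74390 RPM, against 35.5 to 1687). A batch that moves cells and exosomes alike did not account for it in AGS, where the shifts of the third libraries correlated at -0.171 between cells and exosomes (160 miRNAs), but stays possible in SNU-719 (0.447, 152 miRNAs). The shift was shared between the exosomes of the lines more (0.539) than between their cells (0.18), over miRNAs that are not independent replicates, so a difference in the third round of exosome preparation is a hypothesis these data leave open.

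Exosome libraries of both lines carried blood, stromal, liver and endothelial miRNAs, of which 9 were taken for having at least 10 RPM in exosomes of both lines and less than 0.1 of that in the cells, with medians of 1.03 RPM in cells and 144 RPM in exosomes; markers abundant in cells, such as miR-142-3p (210.6 to 813.4 RPM in SNU-719 cells) and miR-143-3p (147.9 to 273.3 RPM in AGS cells), were left out. RNA from 1 outside source of fixed composition, such as serum in the medium, would give 1 ratio of AGS to SNU-719 exosomes for all of these miRNAs (replicates 1 and 2 were compared). The log2 ratios of the 9 had an SD of 1.059, above the replicate SD of 0.324 to 0.396, because miR-122-5p was 39.4-fold higher in AGS exosomes. For the other 8 members the SD was 0.564 (replicate SD 0.405) around a 5.83-fold ratio (2.85 to 8.85). This SD lay within 2 times the replicate SD, the bound for a departure from 1 ratio. These 8 were chosen after the SD of all 9 was seen, so that alone decides nothing. In replicate 3 their log2 ratios had an SD of 0.82 (mean 0.08, -1.06 to 1.36). With 1 library per line there is no replicate SD to judge it by, so an outside source stays undecided for the 8. Release by the cultured cells was not decided, as the cell median of 1.03 RPM was set by the choice, and no medium without cells was analysed here.

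EBV reads were present in the libraries of the EBV-negative line AGS, outside any comparison of viral miRNAs: 69, 53 and 103 in cells and 81, 81 and 62 in exosomes. Carry-over from SNU-719 libraries stays possible: the pooled 449 reads had the composition of a read-weighted mix of SNU-719 libraries (p = 0.067 by 20000 Monte Carlo draws, the only mix that passed among 5 tried on the pooled reads, 10.1% of reads out of place, Spearman 0.921), less so that of SNU-719 cells (p = 0.0081) or exosomes (p = 5e-05, the smallest the draws can give, as for exosome replicates 1 and 2 and for replicate 3) alone. In 6 further comparisons by group, AGS cell reads and AGS exosome reads had Monte Carlo permutation p = 0.084 and 0.063 against SNU-719 cells and 5e-05 each against SNU-719 exosomes and against exosome replicates 1 and 2. A fixed EBV level per human read stays undecided: it differed 1.65-fold between cell and 7.19-fold between exosome libraries, and 63.6% of 132 and 39.8% of 113 human miRNAs of similar level (within 2-fold) differed at least as much. In the reverse direction, the AGS miRNAs miR-371 to miR-373 had 2541 reads in SNU-719 libraries, 118 per 1000000 of their reads in AGS.

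At the preset correlation of camera 4 lists were called for the limma interaction: the 14q32 cluster (median -2.692), the miR-320 family (-2.314), the C19MC and miR-371 cluster (0.838) and the Xq cluster (0.254). With an estimated correlation the adjusted p were 0.94, 0.94, 0.563 and 0.94, and fry called 0. The Xq call was lost without any of the third libraries (adjusted p up to 0.377) and the miR-320 call without AGS exosome replicate 3 (0.146), and the C19MC value mostly restates the AGS change, as 8 of 16 members had too few reads in SNU-719. Over all miRNAs 0 interaction calls were made, so 100 of 100 splits that swap lines within each RNA population have at least as many (highest other 124), which decides nothing.

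Whether any other grouping of the libraries gives as many calls was tested by dividing the 6 libraries of each comparison into 3 and 3 in all 10 ways, where a share below 0.1 cannot be reached. The real split alone had as many calls in 1 of 10 for SNU-719 exosomes against cells (78, highest other 4), for AGS exosomes against cells (1 of 10; 134, highest other 1), for cells of both lines (1 of 10; 173, highest other 0), for exosomes of both lines (1 of 10; 138, highest other 36) and for EBV miRNAs (1 of 10; 5, highest other 0). For exosomes of both lines, the next highest split put AGS exosome replicates 1 and 2 with SNU-719 exosome replicate 1.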

How the results depend on the processing

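Of 233 results for named miRNAs (100 named by rank or as called EBV miRNAs, and the called members of lists), 112 kept direction and call in every setting, 121 lost the call in some and 0 reversed. The planned settings are those fixed beforehand; edgeR, the term for the third replicates, the fit without replicate 3 in any group, the list tests without each library, detection without merging and the block in the list test were chosen after the data were seen. With libraries left out 1 at a time the counts of calls ran from 33 to 155 (SNU-719 exosomes against cells), 60 to 207 (AGS exosomes against cells), 118 to 215 (cells of both lines), 88 to 264 (exosomes of both lines), 0 to 88 (interaction) and 3 to 26 (EBV miRNAs). A group with a library left out has 2, so its spread is borrowed from the other groups. Without replicate 3 in any group they were 341, 368, 360, 421, 286 and 33, and with only the 2 groups in the fit 47, 73, 299 and 69, where fewer libraries set the spread. A term for the third replicates gave 135 for SNU-719 exosomes against cells and 13 EBV miRNAs. The interaction had 3 calls with a pseudocount of 10 RPM and 1 with quantile normalization. With an estimated correlation 0, 0, 1, 0 and 0 lists were called in the 5 comparisons, and with fry 1, 6, 11, 8 and 0. Leaving out 1 library also gave calls to lists not called with all 12: muscle markers (adjusted p = 0.00676 in SNU-719 exosomes against cells, 0.0365 in AGS), the miR-99, miR-100 and miR-125 family (0.0343) and mirtrons (0.0487) in SNU-719, the miR-320 family between cells (0.0353) and between exosomes (0.0174), the miR-200 family between cells (down to 0.0232) and exosomes (0.0283) and miR-17-92 and paralogues between exosomes (0.0269), besides those of the interaction in the report. With all libraries these lists had adjusted p of at least 0.273 with an estimated correlation. Counting any value above 0 as detected, SNU-719 exosomes held fewer miRNAs than cells by -278 and AGS exosomes by -169.3, against 52.33 and 112.7 more at 1 RPM, and without merging by -309 and -182.3 (SNU-719 cells then held 96 more than AGS cells, against 59 at 1 RPM); deeper cell libraries reach more single reads. For the other moved counts the cause was not tested.

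With replicate number as a block 84, 149, 200, 158 and 0 human miRNAs and 9 EBV miRNAs were called. In no comparison does every library correlate best with its own number, so counts that differ with the block are a hint only. It also lost the calls of miR-370-3p, miR-487b-3p and miR-526b-5p in AGS exosomes against cells. The block changed no other call of a named miRNA or list than those given in the report. edgeR shared 50, 92, 112 and 85 calls with limma, 0 in the opposite direction. The change in EBV load, 0.07, turned its sign without SNU-719 exosome replicate 1 (-0.05) or 2 (-0.12) and was 0.37 without replicate 3, 0.35 without replicate 3 in any group and 0.21 with median-of-ratios factors. The lists called in the report kept their direction with other scaling. Depth limits the shallow exosome libraries, where 1 read is up to 1.0039 RPM.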

Other observations

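A further 4 of 760 miRNAs (0.526%) lay higher in every exosome than in every cell library of AGS and lower in every one of SNU-719. If no miRNA differed between exosomes and cells, 1.9 would be expected in each direction, and 0 lay the other way. Many did differ, as the groups did not overlap for 31.2% of miRNAs in SNU-719 and 34.7% in AGS. The expected number therefore cannot judge whether 4 are many or few. All 4 were outside the naming rule and chosen after their values were seen. miR-16-5p, which restrains cell cycle genes, fell by 1.39 in SNU-719 exosomes relative to cells (SE 0.37, limma adjusted p = 0.0362) and had 1.13 in AGS (SE 0.37, adjusted p = 0.0585, not called). Its relative miR-195-5p had -0.998 in SNU-719 and 1.47 in AGS, miR-140-3p -0.47 and 0.66, and miR-29c-5p -1.05 and 0.39, none of them called. The interaction of miR-16-5p was -2.51 (SE 0.53, adjusted p = 0.125), so no difference between the lines was called.

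The let-7 miRNAs, which hold back growth in differentiated cells, together made up 166140, 147150 and 37467 RPM in AGS exosome replicates 1 to 3. In SNU-719 exosomes they made up 118280, 157240 and 35541 RPM, so replicate 3 held the least in both lines.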
